A study of Homo sapiens with 16 samples.

How the data were processed

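RNA abundance was measured on 16 Agilent Human 1A v2 arrays, which carry 60-base probes and read a Cy3-labelled and a Cy5-labelled sample together. Each array set 2 of 4 cell states of U-2 OS, a human osteosarcoma line, against each other: cells with the wild-type glucocorticoid receptor hGRa or with its N363S variant, given vehicle or 10 nM dexamethasone for 6 h. The 4 comparisons were dexamethasone against vehicle in each receptor line and N363S against wild type in each treatment, with 2 biological replicates per comparison and a dye swap for each. The arrays of a dye swap were averaged, with the swapped array turned, so a replicate is 1 value, n = 2 per comparison, and the data hold 8 replicate-level log2 ratios.

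Per the file headers, the authors extracted the scans with Agilent Feature Extraction 7.5 under default settings. The deposited intensity values are mean pixel brightness of each spot and median brightness of its local background, per channel, before background subtraction or dye normalization. The deposited log10 values are the log10 ratio of red over green after the software's own detrending, background subtraction and dye normalization. In the authors' 4 deposited tables of probes shared by both replicates, each probe has a linear ratio and a p_value (p-value) per biological replicate. Folds in these tables were ranked by the size of the mean log ratio over both replicates, so the order within either replicate can differ. The headers name neither the software nor the threshold of these tables, nor the direction of the ratio, which was read from the intensities in the same tables as the second-named RNA over the first.

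Intensities were processed in R 4.3.3 with limma 3.58.1 and the package data.table, version 1.17.8. Spots marked by Feature Extraction as non-uniform or as population outliers were left out, between 1 and 297 per array. Background was corrected by normexp with an offset of 50 added to both channels, which reduces the ratios of probes with low signal. Ratios were normalised by loess within each array with the 1080 control spots at weight 0 and no scaling between arrays. Of 20173 non-control probes on 21073 spots, 19613 were kept because they were well above background in at least 4 of the 8 channels of at least 1 cell state. Spots of the 100 probes present more than once were averaged. Symbols were assigned to 13446 probes, and 6727 had none; 2525 were named from an accession, 7585 from a current symbol, 2946 from an older symbol, 377 from an accession in the authors' tables and 13 from a name there. The genome build of the array design is not stated, so no positions are given; gene order for neighbouring genes came from the reference annotation.

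A linear model with 1 coefficient per comparison was fitted to the 8 ratios with limma (4 residual degrees of freedom, moderated with a prior of 2.99), and the difference between the 2 dexamethasone responses was a contrast of the same fit. Tests were two-sided, and a probe passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison; every adjusted p for a gene is limma's. With 2 replicates an exact sign-change test of a gene could not give a p below 0.5, so no exact test could reach the threshold. Overlaps were tested with one-sided Fisher's exact tests on the probes tested in both comparisons. The 19 gene lists, with 493 symbols, were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, on 11731 genes at 1 probe per gene, adjusted over lists within a comparison. Members were counted with adjustment over all probes and with adjustment over the list alone.

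The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule named NR3C1; the 10 largest rises and the 10 largest falls among passing probes with the same sign on all 4 arrays and 1 gene symbol, or the 5 smallest p where fewer than 5 passed; per list the 4 largest passing members or the member with the smallest p; the glucocorticoid-induced list in both dexamethasone comparisons; and the 5 largest folds of each of the authors' tables. The lists were glucocorticoid-induced genes, inflammatory genes repressed by glucocorticoids, immediate early and AP-1 genes, bone matrix and osteoblast genes, fat cell and lipid storage genes, insulin signalling and glucose metabolism genes, cell cycle genes, apoptosis genes, interferon-stimulated genes, metallothioneins, circadian clock genes, the glucocorticoid receptor with its chaperones and coregulators, unfolded protein and amino acid stress genes, cholesterol synthesis and uptake genes, integrins with cadherins and focal adhesion genes, TGF-beta and BMP pathway genes, WNT pathway genes, markers of other cell types, and housekeeping genes.

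The fit was tested on simulated data made from the arrays' own noise, with 100 probes per comparison given a 2-fold and 100 a 4-fold change. It recovered 85% to 95% of the 2-fold and 99% to 100% of the 4-fold changes, with 4 to 10 false calls per comparison and none in the wrong direction. These shares hold for normal noise drawn anew for each ratio with 200 changed probes, and do not give the sensitivity for the real changes: TIPARP, RGS2 and SGK1 read over 4-fold with dexamethasone in N363S cells and did not pass. For arrays, the number of replicates limits the precision, and no counting depth applies; signal over background per array stands in the report.

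The alternatives were the deposited log10 ratios, median centring in place of loess, no background correction, an offset of 16, Aquantile scaling, no filter and a filter on all 16 arrays, a replicate block, a fit on each comparison's own ratios, the 16 arrays singly with a dye term, a loop model, each dye orientation alone, trend and robust variance moderation, an added threshold of 1.5-fold, and each replicate left out. Added after the data were seen were the left-out spots put back, each replicate alone in the loop model, the 16 arrays singly with extraction day as a block, and the list tests under 3 more normalizations. Leaving out the marked spots had been planned as an alternative; it became the main processing, and its opposite was run instead. A slide or scan date separate from the replicate number was looked for: all 8 arrays of replicate 1 were extracted on 1 day and those of replicate 2 on the other 3 of 4 days, so the planned date block was run on the single arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.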

Results

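The data are transcript abundances in U-2 OS osteosarcoma cells that stably express either the wild-type human glucocorticoid receptor (hGRa) or the N363S variant, from clones selected after transfection. Cells received vehicle or 10 nM dexamethasone, a synthetic glucocorticoid, for 6 h. The 4 comparisons, of 4 arrays each, cover the 4 cell states, and each comparison has 2 biological replicates with a dye swap, so n = 2 throughout and every log2 value is a mean over replicates with its SD. Between 88.4% and 97.4% of spots were well above background in the Cy3 channel and between 85.6% and 98.3% in the Cy5 channel. The number of arrays limits the precision. All 8 arrays of replicate 1 were extracted on 1 day and the 8 of replicate 2 on 3 other days, so the replicate number also marks an extraction batch, and values within each replicate are printed beside the pooled ones.

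The receptor's own transcript was read by 1 NR3C1 probe. Its sequence was not available, so whether it detects the introduced receptor, and with it the receptor level of the lines, is not known. The NR3C1 probe read log2 -0.28 ± 0.01 (SD, n = 2; adjusted p = 0.408) in N363S against wild-type receptor cells in vehicle and -0.47 ± 0.30 (adjusted p = 0.234) in dexamethasone, lower on all 4 arrays of each comparison without passing. With dexamethasone it read -0.03 ± 0.19 in wild-type receptor cells and -0.24 ± 0.21 in N363S cells, neither passing. The 2 dye orientations of replicate 1 in N363S cells gave -1.07 and 0.89 for this probe, so that response is poorly determined.

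Dexamethasone against vehicle in wild-type receptor cells asks which transcripts respond to the hormone through the common form of the receptor. PHACTR3, which encodes a regulator of protein phosphatase 1 and actin, rose 5.43-fold (log2 2.44 ± 0.31, SD, n = 2; adjusted p = 0.0117). ADRA1B, the alpha-1B adrenergic receptor, rose 2.33-fold (log2 1.22 ± 0.07; adjusted p = 0.00468), and MT1A, a metal-binding metallothionein, rose 2.11-fold (log2 1.08 ± 0.17; adjusted p = 0.0394). Each of these 3 genes was higher on all 4 arrays, which the rule for naming the largest rises required. The glucocorticoid-induced list was higher as a group, with a mean log2 of 0.69 and 31 of 34 tested members above 0 (camera adjusted p = 8.10e-28; adjusted p = 0.105 with an estimated correlation). Its mean was 0.64 in replicate 1 and 0.73 in replicate 2. List means, pooled or within a replicate, are over the members with a ratio in every comparison, here 33 genes.

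Within that list 0 members passed over all probes and 20 passed, all higher, when adjusted over the list alone. Among them FOXO1, a transcription factor of glucose metabolism and stress, read 1.95 ± 0.36 (adjusted p = 0.319), NFKBIA, the inhibitor of NF-kappaB, 1.58 ± 0.21 (adjusted p = 0.172), and ZBTB16, a zinc finger repressor, 1.27 ± 0.0039 (adjusted p = 0.210). The chaperone FKBP5 read 0.77 ± 0.08 and the clock gene PER1 0.98 ± 0.22, while ANGPTL4, TAT and IRS2 stayed between -0.04 and 0.01. Signals of ANGPTL4, TAT and IRS2 were low, at log2 6.3 to 6.9, so their flat ratios say little about a response. TAT was well above background on 3 of 4 arrays in each state and IRS2 on 3 of 4 with dexamethasone. DUSP1 had no test in these cells. Metallothioneins were also higher as a group, with a mean of 0.95 over 10 members, 0.74 in replicate 1 and 1.16 in replicate 2 (camera adjusted p = 2.14e-22; adjusted p = 0.105 with an estimated correlation). MT1A alone passed over all probes and 8 passed when adjusted over the list alone; MT1E read 1.53 ± 0.40 and MT1B 1.35 ± 0.35, each with an adjusted p of 0.0664. These genes are so alike in sequence that a probe can detect more than 1 of them. The immediate early gene IER3 read -0.88 ± 0.29 and the matrix protease MMP3 -0.52 ± 0.13, neither passing, and 17 lists did not pass, the TGF-beta and BMP list (mean -0.10, adjusted p = 0.198; 0.0206 with the replicate block and up to 0.886 over 7 alternatives) nearest to it.

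In total 4 of 19290 probes passed in wild-type receptor cells, all 4 higher, and the remaining 1 carries no gene symbol. At an unadjusted p under 0.05 there were 656 probes (406 higher, 250 lower), where chance gives about 964.5. With the comparison's own ratios alone 131 probes passed as higher and 44 as lower. No probe passed with trend and robust variance moderation, without replicate 1 or without replicate 2. With the replicate number as a block 20 probes were higher and 3 lower, including all 4. Counts within 1 replicate alone, given below, come from a loop model with 1 ratio per comparison. The error of that model is technical only if the RNA of a cell state was shared within a replicate number, which the labels do not say.

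The same treatment in N363S receptor cells asks how the variant receptor responds. SPINK13, a serine protease inhibitor of the Kazal type, rose 9.72-fold (log2 3.28 ± 0.23, SD, n = 2; adjusted p = 0.0242) and PHACTR3 rose 7.20-fold (log2 2.85 ± 0.47; adjusted p = 0.00813). NFKBIA rose 3.58-fold (log2 1.84 ± 0.62; adjusted p = 0.0499), with 1.40 in replicate 1 and 2.28 in replicate 2. Rises of 2.87-fold for NKD1, an inhibitor of WNT signalling, 2.86-fold for the collagen gene COL6A1, 2.82-fold for the receptor gene NOTCH4, 2.59-fold for the alpha-tubulin TUBA3E and 2.39-fold for SOD3, the extracellular superoxide dismutase, also passed (adjusted p from 0.0216 to 0.0339). The scaffold gene BAIAP2 (2.19-fold) and the endothelin gene EDN2 (2.04-fold) completed the 10 largest rises. The other probes of NKD1, BAIAP2 and EDN2 read log2 0.37, 0.21 and 0.58. WDR3, a factor of ribosome assembly, fell by 0.95 (log2, SD 0.05; adjusted p = 0.0216), and SYTL2, an effector of vesicle transport, fell by 0.58 (SD 0.09; adjusted p = 0.0420).

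The glucocorticoid-induced list was again higher as a group in N363S cells, with a mean of 0.85 and 32 of 35 members above 0 (camera adjusted p = 9.24e-21; adjusted p = 0.348 with an estimated correlation). Its mean was 0.60 in replicate 1 and 1.10 in replicate 2. Over all probes 3 members rose: NFKBIA, PDK4, a kinase that inhibits pyruvate dehydrogenase (2.04-fold, adjusted p = 0.0484), and TSC22D3, the leucine zipper protein GILZ (2.00-fold, adjusted p = 0.0420). When adjusted over the list alone 23 passed, all higher. TIPARP read 2.80 ± 1.64, RGS2 2.36 ± 1.11, SGK1, a serum- and glucocorticoid-regulated kinase, 2.17 ± 1.18, and FOXO1 2.00 ± 1.02, and none of these passed over all probes. Metallothioneins had a mean of 0.50 over 10 members (0.50 in replicate 1, 0.49 in replicate 2; camera adjusted p = 3.04e-07; adjusted p = 0.448 with an estimated correlation), with 0 of 11 passing over all probes and 7 when adjusted over the list alone. Of the 3 MT2A probes, 1 saturated the scanner on 4 of 4 arrays in vehicle and 3 of 4 in dexamethasone in these cells and 1 on 2 and 3 of 4, so their folds there are not determined; the probe without saturation read 0.43 (adjusted p = 0.645).

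**Figure D1:**
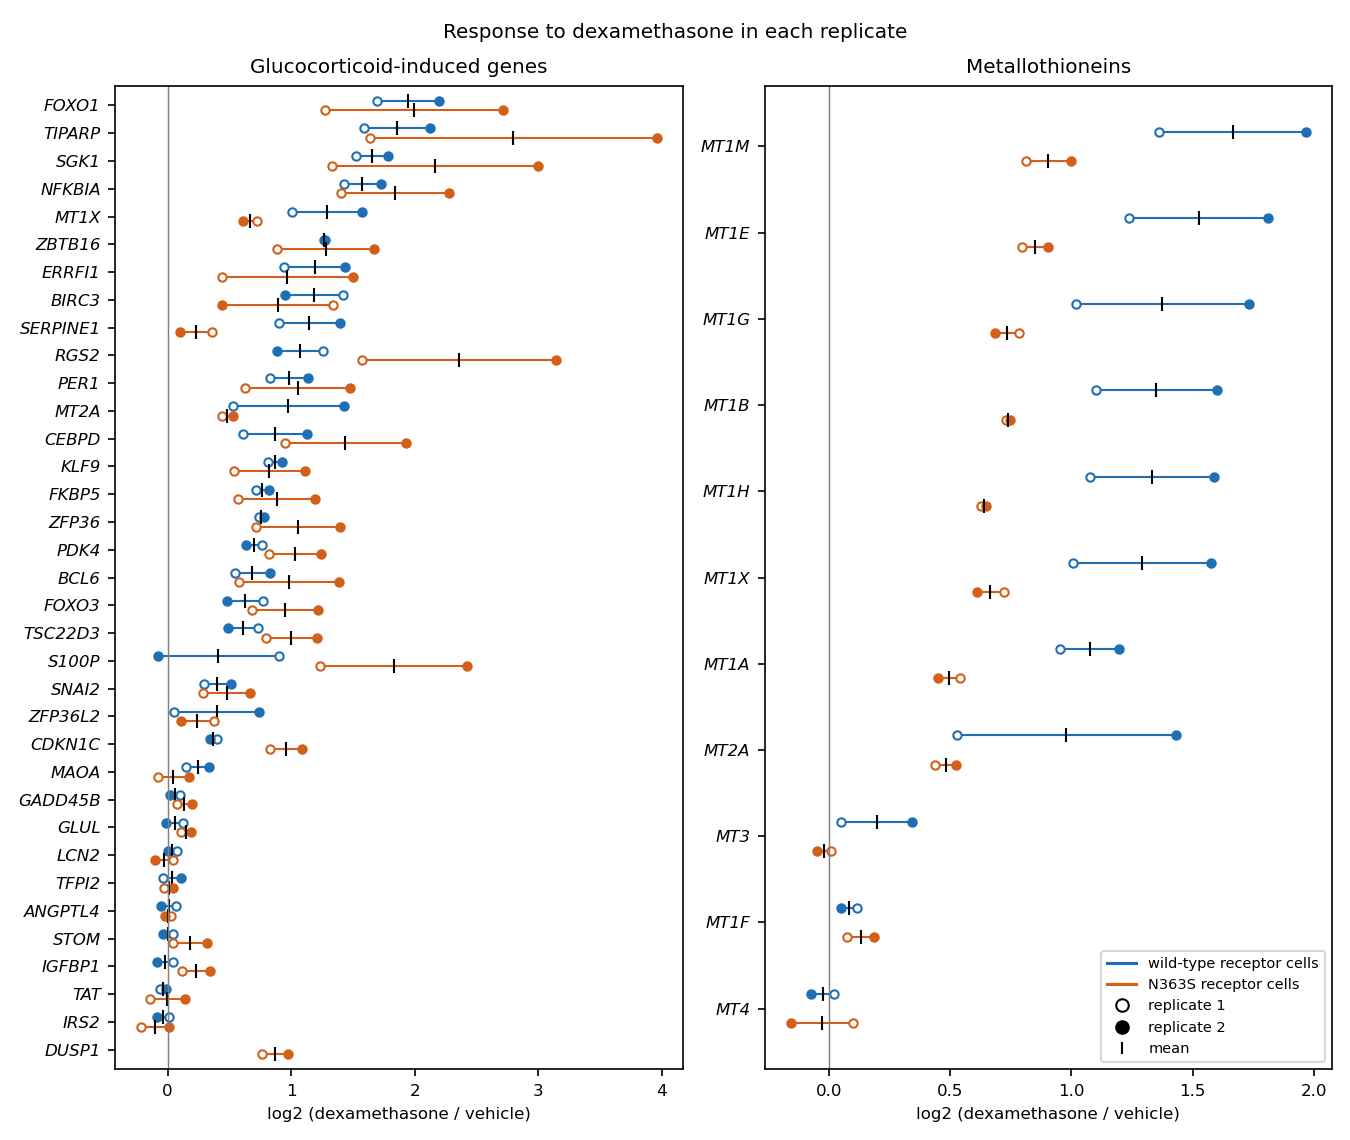
Each symbol is the log2 ratio of dexamethasone over vehicle in replicate 1 (open) or replicate 2 (filled) for members of the glucocorticoid-induced and metallothionein lists, in wild-type (blue) and N363S (orange) receptor cells, with lines joining the 2 replicates and ticks at their mean. TIPARP reached 1.64 and 3.96 in N363S cells, and MT1E read 1.53 in wild-type and 0.85 in N363S receptor cells; the MT2A probe shown was saturated on 3 of 4 arrays in the dexamethasone channel of each line.

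Inflammatory, immediate early and TGF-beta lists were lower as a group with dexamethasone in N363S cells, each with an adjusted p of 0.449 under an estimated correlation. Inflammatory genes repressed by glucocorticoids had a mean of -0.20 (-0.15 in replicate 1, -0.25 in replicate 2; camera adjusted p = 0.00232), and MMP3 read -0.64 ± 0.39. Adjusted over the list alone, 5 of the 32 tested members were lower and 1, TNFAIP3, an inhibitor of NF-kappaB signalling, was higher. Chosen after their values were seen, the other members lower in that count were the cytokine genes IL11 (-1.38) and IL18 (-0.66) and the chemokine genes CCL20 (-0.86) and CCL2 (-0.80). Immediate early and AP-1 genes had a mean of -0.30 (-0.31 and -0.28; camera adjusted p = 0.0413), with IER3 at -1.37 ± 0.32 (adjusted p = 0.0609) and, adjusted over the list alone, 7 of 24 members lower and 2 higher. These 2, named after their values were seen, were the zinc finger gene KLF6 (0.60) and SPRY2 (0.30), a brake on growth factor signalling. TGF-beta and BMP pathway genes had a mean of -0.22 (-0.14 and -0.31; camera adjusted p = 0.0107), with 7 of 27 lower and 2 higher when adjusted over the list alone. The 2 higher were LTBP1, which binds latent TGF-beta, at 0.61 ± 0.10 (adjusted p = 0.0518), and, named after its value was seen, the co-receptor TGFBR3 (0.22). The inflammatory list no longer passed with median centring (adjusted p = 0.0878), and the immediate early list no longer passed with the replicate block (adjusted p = 0.0716), with the mean of a gene's probes (0.0593) or without background correction (0.0910). Over 7 alternatives the adjusted p ranged from 0.00168 to 0.449 for the inflammatory and from 0.0144 to 0.449 for the immediate early list. In wild-type receptor cells 22 of 32 inflammatory members lay below 0 (mean -0.08; camera adjusted p = 0.206). The difference between the lines did not pass for the inflammatory list (-0.12; camera adjusted p = 0.0790) or the TGF-beta list (-0.12; camera adjusted p = 0.132). A fall particular to N363S cells was therefore not shown for the inflammatory and TGF-beta lists.

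In total 20 of 19265 probes passed in N363S cells, 17 higher and 3 lower, against 23 and 9 with median centring; 1 of the 3 lower probes has no approved symbol. At an unadjusted p under 0.05 there were 1716 (888 higher, 828 lower), where chance gives about 963. With the comparison's own ratios alone 200 probes passed as higher and 167 as lower. No probe passed with trend and robust variance moderation or without replicate 2, and 8 passed without replicate 1. With the replicate block 123 were higher and 57 lower, including all 20; within replicate 1 alone the counts were 111 and 93 and within replicate 2 alone 1589 and 1657.

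The direct question of whether the variant changes the response was tested as the difference in dexamethasone response between N363S and wild-type receptor cells. Differences within a replicate, and their SD, set ratios of the same replicate number together, although the labels do not say that the number pairs cultures. The test does not use this pairing. Metallothioneins responded less in N363S cells as a group, with a mean difference over 10 members of -0.46 (-0.24 in replicate 1, -0.67 in replicate 2; camera adjusted p = 9.91e-09; adjusted p = 0.634 with an estimated correlation). Adjusted over the list alone, 7 of 11 members passed, all 7 with the smaller response in N363S cells, and MT1A read -0.58 ± 0.23. A metallothionein probe can detect more than 1 of these genes, so the 7 are not independent. Immediate early and AP-1 genes also differed as a group, by -0.25 (-0.12 and -0.37; camera adjusted p = 0.0140; adjusted p = 0.816 with an estimated correlation), with 0 of 24 members passing when adjusted over the list alone and MYC at -1.27 ± 1.13. The glucocorticoid-induced list differed by 0.16, with -0.04 in replicate 1 and 0.36 in replicate 2, and did not pass (camera adjusted p = 0.0790), although it did with the replicate block (0.0474) and with median centring (0.0379), over a range of 0.0379 to 0.816 in 7 alternatives.

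No single probe passed for this difference by limma, out of 19020, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 293 (138 higher, 155 lower), where chance gives 951. The genes with the smallest p, none passing, were WDR3 (-0.79 ± 0.02), TUBA3E (1.04 ± 0.13), COL6A1 (1.03 ± 0.29), SOD3 (0.81 ± 0.44) and ADRA1B (-0.51 ± 0.00099). These SDs rest on the pairing by replicate number, so the 0.00099 of ADRA1B does not measure the precision of its difference. The count stayed 0 with the replicate block and within replicate 1 alone, and was 1 with the arrays taken singly, 3 with extraction day as a block, and 1378 higher and 1887 lower within replicate 2 alone. Of the 20 probes that passed in N363S cells, all 20 had the same sign in wild-type receptor cells and 19 an unadjusted p under 0.05 there, with a median log2 of 0.60 in wild-type against 1.03 in N363S receptor cells, a contrast that favours the line in which they were called.

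Of the probes called higher with dexamethasone, 3 were shared by the 4 of wild-type and the 17 of N363S receptor cells, where 0.00358 are expected (one-sided Fisher's exact p = 2.37e-09). The shared named genes were PHACTR3 and ADRA1B, and the remaining probe has no symbol. Among falls 0 were shared, since 0 and 3 passed. Genes are not independent replicates, and both comparisons took each probe's residual variance from 1 fit, so their calls are not independent and the expected count and p-value, which assume that they are, describe these probes only.

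N363S against wild-type receptor cells in vehicle asks how the 2 lines differ without hormone; receptor variant and selected clone go together in this design. The largest excess in N363S cells among passing genes was DEFB103B, a beta-defensin whose near-identical copy a probe can also detect, at 2.75-fold (log2 1.46 ± 0.25, SD, n = 2; adjusted p = 0.0391). UNC13D, a gene of granule release, was 2.25-fold higher (log2 1.17 ± 0.40) and CYRIA, which binds the GTPase Rac, 2.23-fold higher (log2 1.16 ± 0.09). MAOA, the monoamine oxidase A gene, was 2.17-fold higher (log2 1.12 ± 0.21; adjusted p = 0.0327), and its other probe read 1.03 ± 0.32 (adjusted p = 0.0702). Also higher were ARHGAP45 (2.18-fold), APMAP (2.11-fold), the vesicle fusion gene VAMP8 (2.11-fold), the actin nucleation gene ARPC3 (2.00-fold), the iron-sulphur cluster scaffold ISCU (1.93-fold) and TMEM263 (1.84-fold).

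Lower in N363S cells in vehicle were the kinase gene MAP3K10 (log2 -0.81 ± 0.14; adjusted p = 0.0379), the collagen COL13A1 (-0.80 ± 0.26), LRCH4 (-0.78 ± 0.05) and the matrix gene EFEMP1 (-0.77 ± 0.05). The N363S channel of MAP3K10 and of LRCH4 was saturated on 1 of 4 arrays, so these 2 deficits rest in part on a capped signal. Smaller deficits passed for RGS4, a brake on G protein signalling (-0.68), the cadherin CDH24 (-0.56), the nucleosome-binding HMGN3 (-0.52), HOXA3 (-0.48) and IFI27L1 (-0.48). Other probes of EFEMP1, RGS4 and CDH24 read 0.02, -0.18 and 0.19. The largest folds in the authors' table for this comparison were of SAA1 and SAA2, acute-phase serum amyloid genes of closely alike sequence, which read 2.80 ± 1.02 (adjusted p = 0.0770; other SAA1 probe -0.12) and 2.34 ± 0.84 (adjusted p = 0.0783), and of HAPLN1, a cartilage link protein gene, at -1.87 ± 1.01 (adjusted p = 0.116), none passing. None of the 19 lists passed, although metallothioneins (mean 0.18) did with median centring (adjusted p = 0.0215; 0.0215 to 0.955 over 7 alternatives). In the integrin, cadherin and focal adhesion list the actin crosslinker ACTN1 read -0.64 ± 0.14 (adjusted p = 0.0561), and 4 of 30 members were lower when adjusted over the list alone, the others, named after their values were seen, being ITGA3 (-0.42), CDH11 (-0.37) and CD44 (-0.22).

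In total 62 of 19249 probes passed in vehicle, 53 higher and 9 lower in N363S cells, against 46 and 2 with median centring. At an unadjusted p under 0.05 there were 2364 (1188 higher, 1176 lower), where chance gives about 962. No probe passed with trend and robust variance moderation, with the comparison's own ratios alone or without replicate 2, and 5 passed without replicate 1 and 8 from the deposited log10 ratios. With the replicate block 265 were higher and 224 lower, including all 62; within replicate 1 alone the counts were 323 and 433 and within replicate 2 alone 2898 and 2931.

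N363S against wild-type receptor cells in dexamethasone asks how the lines differ under hormone. TUBA3E was 2.43-fold higher in N363S cells (log2 1.28 ± 0.01, SD, n = 2; adjusted p = 0.0364), and this gene had risen with dexamethasone in N363S cells. ARHGAP45 was 2.06-fold (log2 1.05 ± 0.05), APMAP 1.85-fold (log2 0.88 ± 0.08) and ISCU 1.81-fold higher (log2 0.85 ± 0.07), each with an adjusted p of 0.0391. The mitochondrial import gene TOMM22 (1.75-fold), the kinetochore gene SPC25 (1.71-fold), the sphingomyelinase SMPD4 (1.64-fold), the splicing factor PRPF6 (1.57-fold), SLC27A5 (1.57-fold) and ENTPD6 (1.57-fold) were also higher. EFEMP1 was lower (log2 -1.01 ± 0.06; its other probe -0.02), and so was HMGN3 (-0.61 ± 0.03), each with an adjusted p of 0.0391. In the authors' table the largest folds were of FLRT3, an adhesion gene, SAA1, FAM90A1, SAA2 and S100P, a calcium-binding protein gene; here they read 2.39 ± 1.42, 2.73 ± 1.39, 1.80 ± 1.58, 2.25 ± 1.21 and 1.62 ± 1.14, none passing.

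Metallothioneins were lower in N363S cells under dexamethasone as a group, with a mean of -0.20 over 10 members (-0.17 in replicate 1, -0.23 in replicate 2; camera adjusted p = 0.0263; adjusted p = 0.520 with an estimated correlation) and 0 of 11 members passing, MT1H at -0.44 ± 0.12. That list no longer passed with the deposited log10 ratios (adjusted p = 0.121) or with median centring (0.154), over a range of 0.0138 to 0.520 in 7 alternatives. Integrins, cadherins and focal adhesion genes were also lower as a group, with a mean of -0.13 (-0.07 in replicate 1, -0.18 in replicate 2; camera adjusted p = 0.0178; adjusted p = 0.520 with an estimated correlation). In that list 3 of 30 members passed, all lower, when adjusted over the list alone: ACTN1 at -0.68 ± 0.25 (adjusted p = 0.0612) and, named after their values were seen, ITGA3 (-0.35) and CD44 (-0.29).

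In total 27 of 19483 probes passed in dexamethasone, 23 higher and 4 lower; 2 of the 4 lower probes have no approved symbol. At an unadjusted p under 0.05 there were 1746 (914 higher, 832 lower), where chance gives about 974. No probe passed with trend and robust variance moderation, with the comparison's own ratios alone, from the deposited log10 ratios, with median centring, without replicate 1 or without replicate 2. With the replicate block 216 were higher and 190 lower, including all 27; within replicate 1 alone the counts were 369 and 465 and within replicate 2 alone 1994 and 2435.

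**Figure D2:**
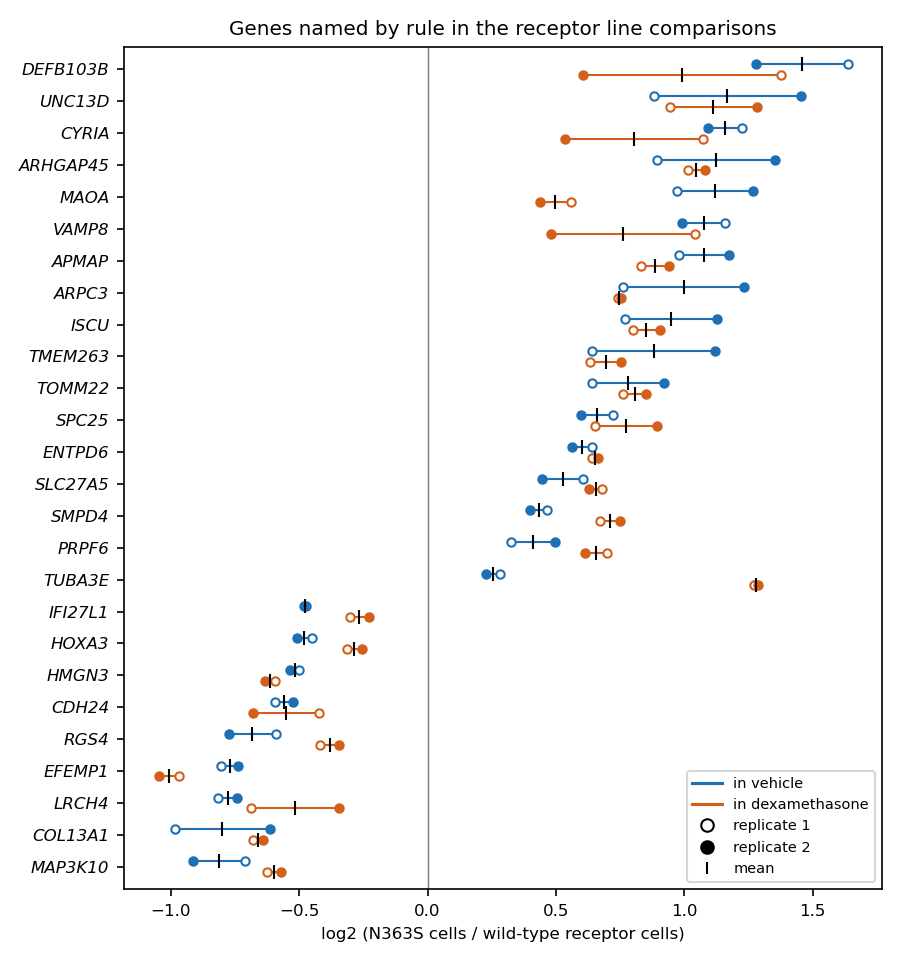
Each symbol is the log2 ratio of N363S over wild-type receptor cells in replicate 1 (open) or replicate 2 (filled), in vehicle (blue) and in dexamethasone (orange), for the genes named among the largest differences, with ticks at the mean. EFEMP1 read -0.77 in vehicle and -1.01 in dexamethasone, and ARHGAP45 read 1.12 and 1.05.

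The line differences were shared between the treatments. Among probes higher in N363S cells 20 were shared by the 52 of vehicle and the 23 of dexamethasone tested in both, where 0.0624 are expected (one-sided Fisher's exact p = 1.22e-50), and they included ARHGAP45, APMAP, ISCU, TOMM22, SPC25 and SMPD4. Among probes lower in N363S cells 2, EFEMP1 and HMGN3, were shared by 9 and 4 (0.00188 expected; one-sided Fisher's exact p = 1.18e-06). All 61 vehicle calls with a test in dexamethasone had the same sign there, as did all 27 dexamethasone calls in vehicle. Both comparisons took each probe's residual variance from 1 fit and their replicate deviations correlated by 0.51, so the calls are not independent, whereas the expected counts and p-values assume that they are. From the deposited log10 ratios 0 were shared, and without a replicate between 0 and 4.

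**Figure D3:**
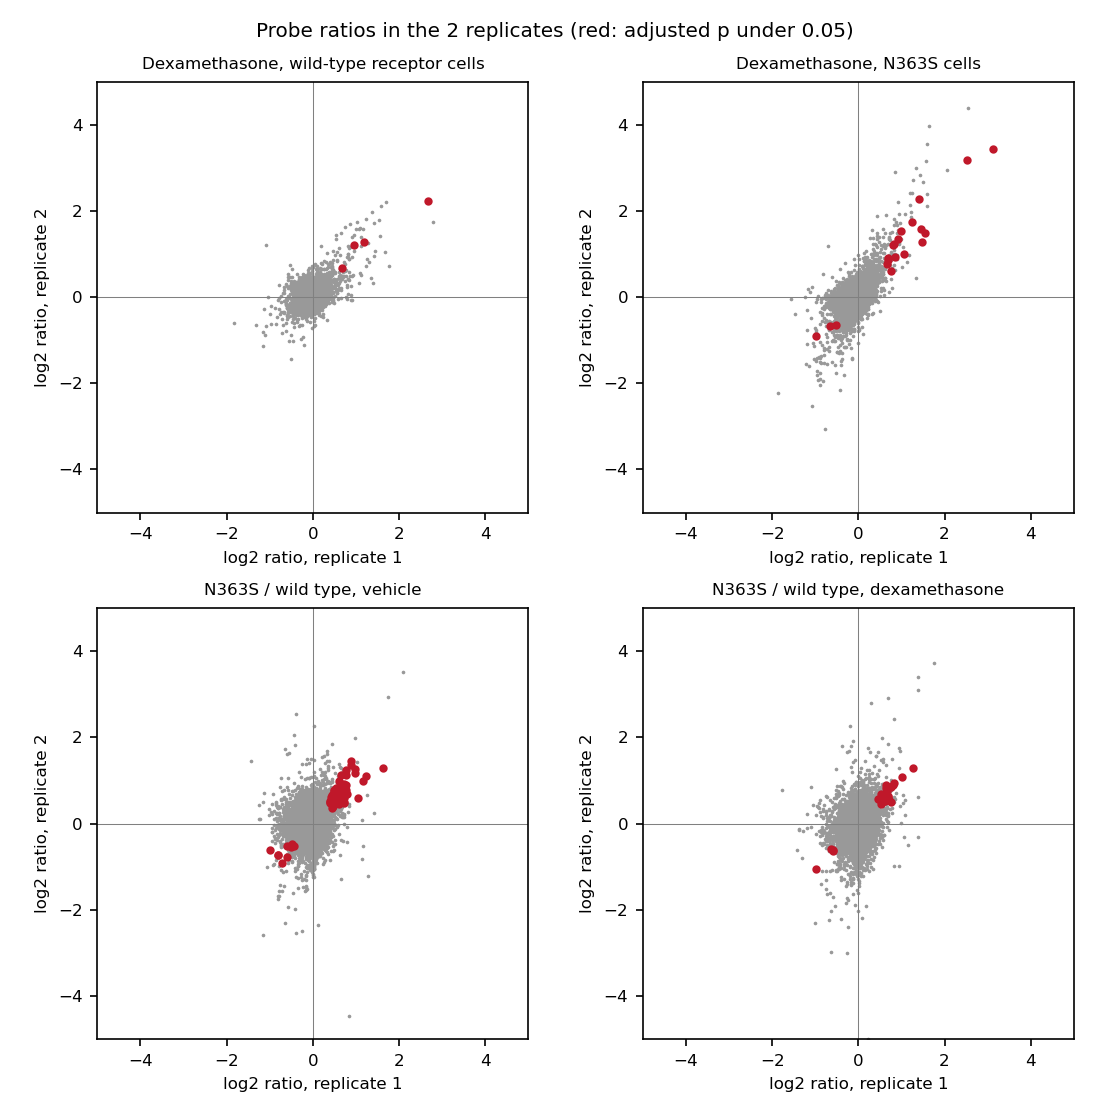
Each point is a probe, with its log2 ratio in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, in the 4 comparisons, and red points passed. Across probes, which are not independent, r between the replicates was 0.32 and 0.59 for dexamethasone in wild-type and N363S receptor cells, and 0.17 and 0.26 for the lines in vehicle and dexamethasone.

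The remaining 13 lists passed in no comparison. The lowest camera adjusted p in any of the 5 comparisons was 0.274 for bone matrix and osteoblast genes, 0.132 for fat cell and lipid storage genes, 0.440 for insulin signalling and glucose metabolism genes, 0.484 for cell cycle genes, 0.337 for apoptosis genes and 0.242 for interferon-stimulated genes. It was 0.135 for circadian clock genes, 0.572 for the receptor with its chaperones and coregulators, 0.106 for unfolded protein and amino acid stress genes, 0.824 for cholesterol genes, 0.207 for WNT pathway genes, 0.785 for markers of other cell types and 0.106 for housekeeping genes. With median centring, and in no other of 7 alternatives, the housekeeping list passed for dexamethasone in wild-type and in N363S receptor cells (adjusted p = 0.00121 and 0.00428, with up to 0.886 and 0.449 in the others). The unfolded protein list then passed for dexamethasone in N363S cells (0.0324) and between the lines in vehicle (0.0452) and dexamethasone (0.0410), with up to 0.756, 0.955 and 0.520 in the others. In 18 of the 95 list tests, none of which passed, the median, the mean and the direction of the test differed in sign; the receptor and chaperone list did so in 4 comparisons.

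The authors' deposited tables are their own calls on these arrays, so a match is not independent evidence. Of the 649 table entries tested here all 649 had the same direction, and 77 passed. By comparison, 3 of 89 passed for dexamethasone in wild-type receptor cells, 12 of 207 in N363S cells, 46 of 178 between the lines in vehicle and 16 of 175 in dexamethasone. Among genes with a symbol, ranked by the mean log2 of columns A and B, SPINK13 led in wild-type receptor cells and FLRT3 in N363S cells. Their dexamethasone ratios in columns A and B were 8.23 and 21.0 for SPINK13 and 46.4 and 9.97 for FLRT3. In column B for N363S cells SPINK13 was larger than FLRT3, at 17.7. The tables do not say which replicate each column is. Across their probes column A was closer to replicate 2 (r = 0.963 and 0.989, against 0.918 and 0.917 with replicate 1) and column B to replicate 1 (0.973 and 0.983, against 0.850 and 0.925) in these 2 tables. In the ratios computed here SPINK13 read log2 2.26 ± 0.75 in wild-type receptor cells (adjusted p = 0.188) and FLRT3 3.47 ± 1.30 in N363S cells (adjusted p = 0.0900), neither passing.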

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

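Among the tests weighed here, those of array noise and of the vehicle level for the metallothioneins and that of compression for the replicates were chosen only after the result was seen.

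The difference in dexamethasone response between the lines was negative as a group for metallothioneins (-0.48 over 11 members) and for immediate early and AP-1 genes (-0.25), tested as an interaction at a preset correlation; neither held with an estimated correlation. For metallothioneins, scanner saturation was excluded, since only 13.3% of the list's probes (2 of 15) were saturated in the dexamethasone channel on at least 2 of the N363S arrays. The receptor arrays gave -0.22 and -0.53 for the same difference in the 2 replicates, over the 10 members with a ratio in every comparison. The smaller response was therefore not confined to the dexamethasone arrays. Noise of the dexamethasone arrays was not excluded, since this test and its bound were chosen after the result was seen. RNA may also have been shared within a replicate number, so other cultures were not tested. Against wild type, these 10 members read -0.17 and -0.23 in dexamethasone and 0.05 and 0.31 in vehicle. A higher vehicle level in N363S cells as the whole cause was not excluded, since this test was chosen after the result was seen. The deficit in dexamethasone kept a mean of -0.20 to -0.16 over 7 alternatives. It did not pass with the deposited log10 ratios (camera adjusted p = 0.121), median centring (0.154) or an estimated correlation (0.520). A weaker induction in the N363S line is possible, but receptor variant, clone and receptor protein level go together here and stay untested.

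Ratios were larger in replicate 2 than in replicate 1. Compression of all replicate 1 ratios by 1 factor would give both lists the same mean in replicate 1 over that in replicate 2. In wild-type receptor cells it was 0.64 for metallothioneins and 0.877 for the glucocorticoid-induced list (difference -0.24, 95% interval over list members -0.45 to -0.082). In N363S cells it was 1.02 and 0.55 (0.47, 0.30 to 0.74), the other way round. These values argue against 1 factor as the whole cause but do not exclude it. The interval holds no error between replicates, and a metallothionein probe can detect more than 1 of these genes. For RNA of the 2 lines mixed in replicate 1, probes higher in N363S cells shrank to 0.25 (126 probes) and probes higher in wild-type cells to 0.20 (171 probes), a difference of 0.050, but these were selected for being apart in replicate 2 and so shrink alike without mixing. Against mixing as the whole cause, 62 probes apart in replicate 1 in dexamethasone were larger in replicate 1 also in vehicle (medians 0.79 and 0.22, a ratio of 3.66), but these were selected in replicate 1, and replicate deviations are shared between the receptor comparisons (r = 0.51), so this decides nothing either. Mixing, compression and drift between cultures cannot be told apart here, since the labels do not describe the cultures behind each replicate. No biological explanation was tested.

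The 2 dye orientations of replicate 1 gave opposed ratios across probes, with r from -0.52 to -0.12 over the 4 comparisons, against 0.08 to 0.58 in replicate 2. Probe-specific dye bias had the values it needs, since the dye parts of the 4 replicate 1 comparisons shared a mean r of 0.707 (0.475 to 0.826; mean 0.563 in replicate 2). An exchanged dye label was excluded, since probes with large ratios in replicate 2 kept a median of at least 0.18 on each of the 8 replicate 1 arrays. A candidate explanation is therefore dye bias, which averaging over the dye pair is meant to remove, and the design names no biological one.

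Chance gives 1 outlying array in about 1 of 20 groups of 4, which is 10 of the 200 gene groups tested, and 10 were found. DEFB103B in the vehicle receptor comparison read 0.92 on the first array of replicate 2 and 1.58 to 1.69 on the others. HSP90AA1 in the same comparison and on the same array read -0.057, against -0.42 to -0.36. With dexamethasone in wild-type receptor cells, FOXO3 read 0.21 on the first array of replicate 2 (others 0.76 to 0.77) and IFI44L 0.47 (0.03 to 0.09). On the first array of replicate 1 there, STOM read 0.11 (others -0.05 to -0.02) and PTH1R -0.11 (0.48 to 0.52). With dexamethasone in N363S cells, 4 genes stood apart on the first array of replicate 1: DUSP1 at 0.48 (0.96 to 1.05), ERRFI1 at -0.72 (1.39 to 1.61), BCL6 at -0.39 (1.27 to 1.54) and IRS2 at -0.40 (-0.03 to 0.01).

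Of 20 array quantities, 3 had an array far from the others of its comparison. The first array of replicate 1 between the lines in vehicle had 297 spots marked by the extraction software, against 18 to 45. The second array of replicate 2 with dexamethasone in N363S cells had 42 saturated spots, against 21 to 24, and 98.3% of its Cy5 spots were well above background, against 91.6% to 92.7%.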

How the results depend on the processing

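The replicate alone in the loop model, the arrays singly with extraction day as a block, the left-out spots put back, and the list tests with median centring, without background correction or with an offset of 16 were chosen after the data were seen; the other alternatives were planned. Counts are of passing probes. The 4 calls with dexamethasone in wild-type receptor cells became 15 from the deposited log10 ratios, 2 with median centring, 10 with an offset of 16, 1 with the filter on all 16 arrays, 23 with the replicate block, 175 with the comparison's own ratios only, 83 with arrays singly and a dye term, 37 with extraction day as a block, 32 in the loop model, 50 in replicate 1 alone, 2143 in replicate 2 alone, 1 from the first arrays of each dye pair, 0 with trend and robust moderation, and 0 to 0 without a replicate. The 20 calls in N363S cells became 32 with median centring, 9 without background correction, 52 with an offset of 16, 10 with the filter on all 16 arrays, 180 with the replicate block, 367 with own ratios only, 505 with arrays singly, 310 with the day block, 320 in the loop model, 204 in replicate 1 alone, 3246 in replicate 2 alone, 0 from the first and 40 from the second arrays of each dye pair, 0 with trend and robust moderation, and 0 to 8 without a replicate.

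The 62 calls between the lines in vehicle became 8 from the deposited log10 ratios, 32 with an offset of 16, 489 with the replicate block, 0 with own ratios only, 539 with arrays singly, 181 with the day block, 461 in the loop model, 756 in replicate 1 alone, 5829 in replicate 2 alone, 0 from the first and 4 from the second arrays of each dye pair, 0 with trend and robust moderation, 37 at 1.5-fold, and 0 to 5 without a replicate. The 27 calls in dexamethasone became 0 from the deposited ratios and with median centring, 5 with an offset of 16, 13 with the filter on all 16 arrays, 406 with the replicate block, 0 with own ratios only, 448 with arrays singly, 255 with the day block, 491 in the loop model, 834 in replicate 1 alone, 4429 in replicate 2 alone, 0 from either dye orientation, 0 with trend and robust moderation, and 0 to 0 without a replicate. The difference in response, with 0 calls, had 1 with arrays singly, 3 with the day block, 3265 in replicate 2 alone, and 0 to 0 without a replicate. Fits of 1 replicate alone have 1 residual degree of freedom. Their error is technical only if the RNA of a cell state was shared within a replicate number, which the labels do not say. Single arrays treat dye pairs by a correlation (0.0355, or 0.0415 with the day block). The filter on all 16 arrays tests fewer probes, and a left-out replicate leaves fewer ratios. Own ratios take the error from the comparison alone, whereas the main fit shares 1 error over the 4 comparisons. With own ratios the dexamethasone calls rose to 175 and 367, and the receptor line calls fell to 0. The larger counts between the lines than with dexamethasone thus depend on the shared error, and the order was reversed without it. For the remaining changes the cause was not tested. Without a replicate, the lone ratio is assumed to vary like the other comparisons.

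The 3 shared dexamethasone calls became 8 from the deposited ratios, 19 with the replicate block and 0 to 2 without a replicate; the 22 shared receptor line calls became 0 from the deposited ratios, 13 at 1.5-fold, 247 with the replicate block and 0 to 4 without a replicate. Of the 95 list tests 11 passed, 0 with an estimated correlation, and 10 to 16 in the other alternatives; the means of those 11 kept their sign in all 7 alternatives. Of the authors' 649 tested entries 77 passed here, and 28 from the deposited ratios, with all 649 in the same direction. Deviations of the replicates from their mean correlated by 0.51 between the 2 receptor comparisons and by -0.24 to 0.24 between the other pairs. The difference in response from the dexamethasone arrays and that from the receptor arrays were closer with the same replicate number (SD of their gap 0.18 and 0.17, r = 0.16 and 0.69) than across numbers (SD 0.25 and 0.25, r = 0.16 and 0.04), a hint from the data that RNA was shared within a number, which the fit, taking the 8 ratios as independent, leaves out. The labels do not say that the number pairs cultures, so the block stayed an alternative. With the block all 4, 20, 62 and 27 calls of the 4 comparisons were kept.

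Named genes were counted as unchanged in 3814 cases over the alternatives, as newly passing in 516, as no longer passing in 371 and as reversed in 30. Where neither setting passed, a sign change no larger than the SD between replicates was counted as unchanged. The 30 therefore leave out such small sign changes. With median centring GLUL read -0.097 and -0.0064 with dexamethasone in wild-type and N363S receptor cells, and in wild-type cells GADD45B read -0.013, IRS2 0.10 and TAT 0.12. In wild-type cells with dexamethasone STOM read -0.0835 with the day block, and ANGPTL4 -0.13, LCN2 -0.059 and TAT 0.018 in replicate 2 alone; from the first arrays of each dye pair ANGPTL4 read -0.15, TAT 0.14 and MVD -0.079; TFPI2 read -0.10 from the deposited ratios and -0.094 from the second arrays. In N363S cells MAOA read -0.19 with the day block and -0.18 from the first arrays, ANGPTL4 -0.15 from the first arrays, and GLUL -0.083, TFPI2 -0.10 and NR3C1 0.30 from the second arrays. For the difference in response LPIN1 read -0.017 and CSNK1E 0.037 from the first arrays, ITGA6 0.011, LDHA 0.46 and NR3C1 0.39 from the second arrays, MX2 -0.022, WNT11 -0.12 and CD14 0.032 from the receptor arrays, and WNT11 -0.041 in replicate 1 alone. Between the lines in dexamethasone EPCAM read -0.022 from the first arrays. For these the cause was not tested. Signal over background limits TFPI2, which was not well above background with dexamethasone in wild-type receptor cells.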

Other observations

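In the unfolded protein and amino acid stress list, HSP90B1, a chaperone of the endoplasmic reticulum, read log2 0.84 ± 0.35 (SD, n = 2; adjusted p = 0.0532) in N363S against wild-type receptor cells in vehicle and 0.76 ± 0.12 (adjusted p = 0.0916) in dexamethasone. In dexamethasone 3 of the list's 17 tested members were higher when adjusted over the list alone, and in vehicle 1 of 18. ATF4 (0.50) and DNAJB9 (0.35), the other 2 in dexamethasone, were named after their values were seen. Among interferon-stimulated genes the immunoproteasome subunit PSMB8 read 0.46 ± 0.02 in vehicle (adjusted p = 0.0518) and 0.33 ± 0.04 in dexamethasone (adjusted p = 0.123).

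A hypothesis was that genes called between the receptor lines lie next to each other, as a difference in copy number of chromosome segments between clones would give; both tests were set down before their results were seen. Of the 58 called genes with a place in the annotation, 25 had another call of the same direction within 10 measured genes, where 10000 random gene orders gave a median of 4 and at most 17 (permutation p = 1e-04, the smallest they can give), so chance placement was excluded. The calls formed 6 groups, all higher in N363S cells, the largest with 10 calls from NUP37 to VPS29, among them TDG, TMEM263, ISCU, KCTD10, ANAPC7 and ARPC3, and the next with 5 from SPC25 to OLA1 and 4 from MAP3K2 to IMP4. The 77 uncalled genes lying between calls had medians of 0.06 and 0.12 in vehicle and 0.05 and 0.05 in dexamethasone between the lines. With dexamethasone against vehicle their medians were -0.01, -0.01, -0.02 and -0.04. The receptor medians, the lowest 0.048, met the outcome set beforehand as counting against a copy number difference. That rule was set aside only after its result was seen, because the genes between calls leave out the called genes themselves. A copy number difference therefore stays open, and the shares that follow were not part of the rule set beforehand. Of the 77 uncalled genes 42.9% were shifted in the direction of the calls in all 4 receptor ratios. For other uncalled genes the mean of the shares all higher and all lower was 12.7%, so their share shifted either way is larger. Most of the genes shifted in the direction of the calls lay in the largest group, with 20 of its 35 uncalled genes. The other groups had 5 of 17, 3 of 8, 4 of 9, 1 of 6 and 0 of 2. In 3 of the 6 groups 1 receptor median of the uncalled genes lay below 0 (-0.0076 from MAP3K2 to IMP4, -0.037 from APMAP to ENTPD6 and -0.026 from TOMM22 to APOBEC3C), so the shift was not shown for every group.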
